A study of Homo sapiens with 8 samples.

How the data were processed

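RNA of the Panc-1 sublines Panc-1-P and Panc-1-CTC, from dish culture and from subcutaneous growth in mice, was hybridised to 8 Agilent 1-colour arrays, 2 for each of the 4 groups. Per the labels' protocols, total RNA was isolated with a phenol reagent, treated with DNase, and 0.5 ug of it was amplified and labelled with Cy3. The deposited files hold a processed intensity per spot which, per the file headers, Agilent Feature Extraction made by background subtraction and detrending within each array, with no normalization between arrays. The file headers name version 10.7.1.1 of that software and array design 028004, while the submitters' processing notes name version 9.1. All arrays came from 1 slide and 1 scan, per the file headers, so there was no slide or scan batch to test. The in vitro arrays lay in 1 row of the slide and the in vivo arrays in the other.

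Control spots and spots flagged as non-uniform or population outliers were left out, the log2 values of the spots of 1 probe were averaged, and 1 probe flagged on an array in every spot was dropped. The log2 of the processed signal minus the array's 75th percentile over all remaining probes was used. A probe was kept when it was well above background, by the files' own flag, on both arrays of at least 1 group, which left 25351 probes. Probe accessions were matched without versions to a RefSeq gene table of assembly GRCh38.p14, which paired 24910 probes with 1 symbol and left 17494 with none. A gene with several kept probes (3183 genes) was represented by the one with the highest mean signal, and probes without a symbol were tested on their own, giving 21577 features. Brightness over background limits which genes were measured in vitro.

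Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with 1 mean per group over all 8 arrays, which leaves 4 residual degrees of freedom and a prior of 1.59. The contrasts were Panc-1-CTC minus Panc-1-P in vitro, in vivo and over both settings, in vivo minus in vitro in each subline and over both, and the interaction. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the tested features, with a threshold of 0.05. Errors are standard errors of the fit. Where a group was not well above background, the fold is a bound, the bright group's mean against the mean over the dim group's arrays of the higher of the lowest signal well above background and the probe's own signal. Such a bound holds for the scaling used and moves with it. Of 45 gene lists fixed beforehand, those with at least 5 tested members were tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation, adjusted over the lists tested.

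Before the data were examined, the following were fixed: the comparisons, the gene lists, the alternatives and the rule for named genes. The rule names the 8 largest rises and falls of each subline comparison and of in vivo against in vitro among genes past the threshold, above background in the higher group and with arrays that do not overlap, the 5 largest interactions in each direction, up to 4 members of a list by adjusted p, and a fixed set of 14 genes. Symbols of uncharacterised loci were counted and not named, as were symbols on a list fixed beforehand.

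The fit and the list test were tried on simulated data drawn from the group means and residual spread of the 21577 features, with the compared groups set to the same mean and 200 genes changed by known amounts. For the in vivo comparison the fit called 17.9% of genes changed 1.5-fold, 40.3% of those changed 2-fold and 53.03% of those changed 4-fold, with 9.76% of the 82 calls false, more than the 5% aimed at. For the in vitro comparison these shares were 19.4%, 44.8% and 74.2%, with 2.13% of 94 calls false, and for in vivo against in vitro 34.3%, 52.2% and 87.9%, with 6.45% of 124 calls false. A list shifted by 0.5 was called in each simulated comparison, and no unchanged list was. The noise was drawn for each gene on its own, so the simulation does not test list calls where genes correlate. It began after scaling, the background filter and the choice of probes, so it does not test those steps. With only 200 of 21577 features changed and no trend with signal level, its shares need not hold for the real comparisons.

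Alternatives were quantile normalization, median centring, normexp background correction (offset 50) with quantile normalization or the 75th percentile, no filter on dim probes or only probes above background on all 8 arrays, flagged spots kept, the mean of all probes or every probe on its own, a replicate block, only the arrays compared, an intensity trend with robust fitting, array weights, and leaving out each array. The planned normexp used the mean spot signal, which the files lack, so the median spot signal took its place. After the data were seen, the 75th percentile over probes above background on all 8 arrays, counts by background in the compared groups, and the list test on the in vivo arrays alone were added. The RefSeq table was also used for the order of genes along chromosomes. Figures were drawn with matplotlib 3.10.9.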

Results

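Gene expression was measured in 2 sublines of Panc-1, a human cell line from pancreatic ductal adenocarcinoma. The labels call Panc-1-P the low malignant subline and Panc-1-CTC the highly malignant one. Each subline was sampled in 2 settings, in dish culture (in vitro) and after subcutaneous injection in mice (in vivo), with 2 arrays in each of the 4 groups. All 8 arrays were 1-colour Agilent arrays on 1 slide. Every array carried 42404 probes that entered the analysis, of which 24910 were paired with 1 gene symbol. After dim probes were left out, 21577 genes or unnamed probes were tested, 13683 of them with a symbol.

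The arrays did not reach the same signal. In vivo, 59.3% of the probes were well above background on the Panc-1-P arrays and 58.4% on the Panc-1-CTC arrays (means, n = 2 each). In vitro the means were 17.6% for Panc-1-P and 34.5% for Panc-1-CTC. The 75th percentile of the intensity was 18.2 and 17.1 on the Panc-1-P in vitro arrays, 58.1 and 61.3 on the Panc-1-CTC in vitro arrays, 442 and 421 on the Panc-1-P in vivo arrays, and 543 and 553 on the Panc-1-CTC in vivo arrays. On the Panc-1-P in vitro arrays this percentile lay under the lowest signal called well above background, 24.4 and 23.9. Spike-in probes varied less, with mean log2 signals from 13.32 to 13.95 over the 4 groups, and ribosomal RNA probes from 16.50 to 16.98. Across the 6093 probes well above background on all arrays, the group means correlated at r = 0.989 between the sublines in vivo and at r = 0.703 in vitro. Panc-1-CTC in vitro correlated at r = 0.853 with Panc-1-P in vivo and r = 0.840 with Panc-1-CTC in vivo. Panc-1-P in vitro reached only r = 0.436 with Panc-1-P in vivo and r = 0.394 with Panc-1-CTC in vivo, so that group stood apart. These correlations are across probes, which are not independent replicates.

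**Figure D1:**
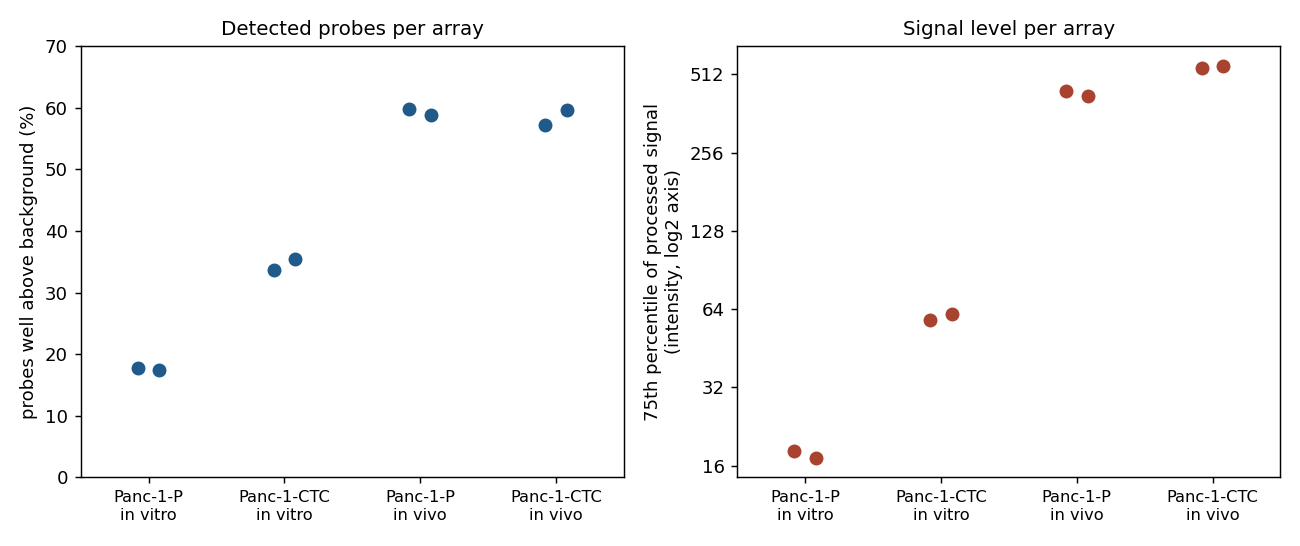
Share of probes well above background (left, percent) and 75th percentile of the processed signal (right, intensity on a log2 axis) for each array, with 1 point per array and 2 arrays per group. The Panc-1-P in vitro arrays had 17.8% and 17.4% of probes above background, and the in vivo arrays lay between 57.2% and 59.7%.

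The series asks which genes differ between the highly and the low malignant subline, and in vivo the arrays of both were of similar brightness. Panc-1-CTC tumours had much more RNA of FGR, a SRC-family kinase, at least 83.6-fold, and of SNAI2, a transcription factor that represses epithelial genes, at least 9.38-fold. SPOCK1, an extracellular proteoglycan, was higher by 5.85 ± 0.12 log2, and CALD1, an actin-binding protein of contractile and mesenchymal cells, by 4.75 ± 0.08. Panc-1-P tumours had more SORBS2, an adaptor of the actin cytoskeleton, at least 48.8-fold, more SPP1 (osteopontin), at least 8.17-fold, and more DSP (desmoplakin), which fell by 4.30 ± 0.26 in Panc-1-CTC. CDH2 (N-cadherin) fell by 2.08 ± 0.11 in Panc-1-CTC, while CDH1 (E-cadherin) rose by 0.94 ± 0.08. Fold changes are Panc-1-CTC over Panc-1-P on the log2 scale with their standard errors, from 2 arrays per group throughout, and "at least" gives a bound where 1 group was not well above background. The bounds hold for the scaling used.

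With limma's moderated test, 5458 of the 21577 tested features differed in vivo at an adjusted p under 0.05, 2450 higher and 3008 lower in Panc-1-CTC. Of these, 787 were higher and 842 lower by at least 2-fold. Among the 19460 features well above background in both groups, 2125 were higher and 2587 lower. The split into higher and lower calls depended on the scaling. Centring on the median gave 2386 higher and 1305 lower, and normexp background correction with the 75th percentile gave 4674 higher and 7552 lower.

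The 8 largest rises in Panc-1-CTC in vivo also included the water-channel pseudogenes AQP7P3 (6.61 ± 0.15) and AQP7P1 (6.12 ± 0.16), MOXD1 (5.51 ± 0.13) and MGST1, a microsomal glutathione transferase (5.67 ± 0.11, above background on 1 of the 2 Panc-1-P arrays). APCDD1L was at least 15.5-fold and SELENBP1, a selenium-binding protein, at least 20.96-fold higher. The largest falls included PDLIM3, a muscle actinin-binding protein (at least 23.9-fold), HAPLN1, a hyaluronan link protein (at least 17.8-fold), FAM149A (at least 9.64-fold) and IL3RA, the interleukin-3 receptor alpha chain (at least 10.97-fold). FSTL5 fell by 5.12 ± 0.09, and RHOH fell by 4.46 ± 0.12 with 1 of the 2 Panc-1-CTC arrays above background. Adjusted p for these 16 genes and SNAI2 ranged from 1.3e-05 to 0.000337. Among the other genes fixed for naming, the receptor kinase gene MET was higher by 1.52 ± 0.08 (adjusted p = 0.000225) and KRT19 by 1.44 ± 0.19 (adjusted p = 0.00509). CXCR4, a chemokine receptor, was lower with a log2 fold change of -1.20 ± 0.10 (adjusted p = 0.000981). Small falls passed for CDKN2A (-0.63 ± 0.14), ACTB (-0.41 ± 0.07) and VIM (-0.33 ± 0.08), and each of these 3 calls was lost when any 1 in vivo array was left out. The log2 fold changes of EPCAM (-0.31, adjusted p = 0.231), CD44 (0.21, adjusted p = 0.202), ZEB1 (-0.13, adjusted p = 0.823) and the proliferation marker MKI67 (-0.05, adjusted p = 0.742) did not pass the test. HBA1, also fixed for naming, had no tested probe.

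**Figure D2:**
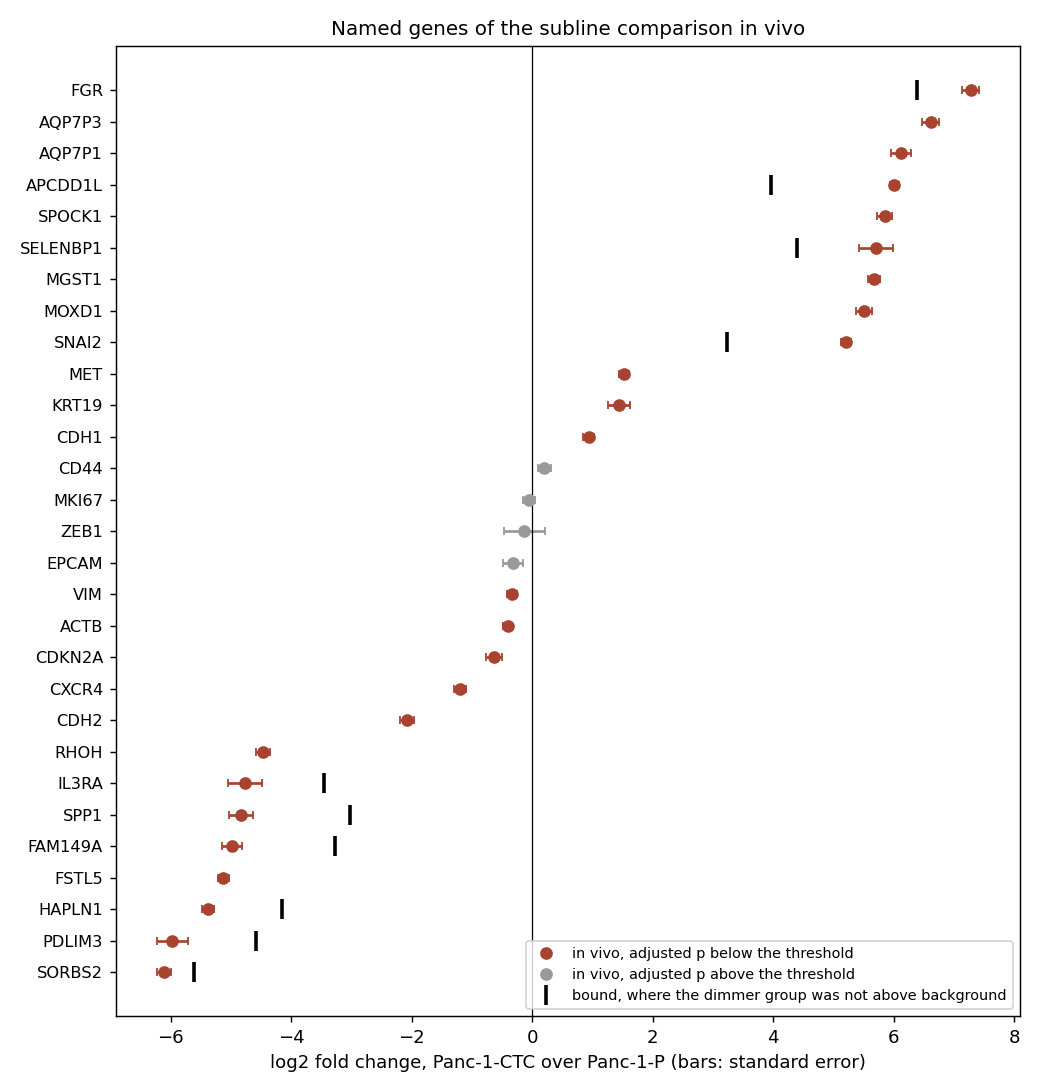
In vivo log2 fold change of Panc-1-CTC over Panc-1-P for the 8 largest rises, the 8 largest falls and the genes fixed for naming (points, with standard errors as bars, 2 arrays per group; grey where the adjusted p was above 0.05). Black ticks mark the bound for genes whose dimmer group was not well above background, as for FGR at least 83.6-fold and SORBS2 at least 48.8-fold.

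Gene lists fixed before the data were examined were tested with camera, limma's competitive test of a list against all other genes, at a preset correlation of 0.01. In vivo, 13 of 43 testable lists were higher and 3 lower in Panc-1-CTC at an adjusted p under 0.05. None of these 16 calls held with a correlation estimated from the residuals, where the unadjusted p of the strongest, cholesterol synthesis, was 0.0053, and 7 had an unadjusted p under 0.05. The list results rest on the preset value. Among the other settings tried, 6 of the 16 kept their call in every one in which they could be tested: amino acid starvation, cholesterol synthesis (too few members above background on all 8 arrays to be tested there), replication-dependent histones, the G2/M list, the S phase list and the unfolded protein response.

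Genes of the amino acid starvation response and serine synthesis were higher in Panc-1-CTC tumours. Of 24 tested members 10 rose, none fell and 14 did not pass (14 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 0.50. They included PHGDH, the first enzyme of serine synthesis (1.36 ± 0.07), the cystine carrier SLC7A11 (1.37 ± 0.07), the amino acid carrier SLC7A5 (0.97 ± 0.10) and the stress protein NUPR1 (1.57 ± 0.08). The camera test gave adjusted p = 2.16e-06, and adjusted p = 0.196 with an estimated correlation. Genes of cholesterol synthesis and targets of SREBP2, its main transcription factor, were also higher. Of 24 members 12 rose, 1 fell and 11 did not pass (15 and 1 adjusted over the list alone), with a median of 0.50. The cholesterol carrier STARD4 rose by 3.001 ± 0.15, INSIG1, which holds back SREBP activation, by 1.31 ± 0.15, and the synthesis enzyme EBP by 0.84 ± 0.08. The list gave adjusted p = 1.35e-05, and adjusted p = 0.196 with an estimated correlation. In the unfolded protein response, 11 of 28 members rose and 1 fell (11 and 2 adjusted over the list alone), among them the chaperone DNAJB11 (0.85 ± 0.09), the disulphide isomerase PDIA6 (0.76 ± 0.07) and the transcription factor XBP1 (0.62 ± 0.09). That list gave adjusted p = 0.00301, and adjusted p = 0.296 with an estimated correlation.

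Cell cycle lists rose by small amounts. In the G2/M and mitosis list 10 of 34 members rose, none fell and 24 did not pass (11 and 0 adjusted over the list alone), with a median of 0.24. CDC20, an activator of the anaphase-promoting complex, rose by 0.81 ± 0.08, the checkpoint kinase BUB1 by 0.65 ± 0.07 and the mitotic kinase PLK1 by 0.57 ± 0.08 (its other probe gave -0.06), while MKI67 is given above as not passing. The list gave adjusted p = 0.000112, and adjusted p = 0.196 with an estimated correlation. In the list of DNA replication and S phase 14 of 40 members rose and 3 fell (15 and 3 adjusted over the list alone). RFC2 (0.70 ± 0.08) and POLE2 (0.77 ± 0.10), parts of the replication machinery, rose, and CCNE2 (cyclin E2) fell by 0.58 ± 0.07. That list gave adjusted p = 0.00142, and adjusted p = 0.275 with an estimated correlation. Replication-dependent histones, whose RNA is made mainly in S phase, went the other way. None of 50 members rose, 14 fell and 36 did not pass (0 and 17 adjusted over the list alone), with a median of -0.30. H2BC6 (-0.64 ± 0.08) and H2BC5 (-0.50 ± 0.09) were among them, and both calls were lost with median centring, that of H2BC5 also without any 1 of 3 in vivo arrays. The histone list gave adjusted p = 1.35e-05, and adjusted p = 0.404 with an estimated correlation.

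Genes of the mesenchymal state and of the matrix moved in both directions. Of 33 mesenchymal genes 14 rose and 6 fell (15 and 6 adjusted over the list alone), with CALD1, the secreted glycoprotein FSTL1 (3.69 ± 0.08) and SNAI2 among the rises and CDH2 and VIM among the falls. The list gave adjusted p = 0.00301, and adjusted p = 0.41 with an estimated correlation. It no longer passed when only probes above background on all 8 arrays were tested, where SNAI2 and other dim genes drop out and the median was -0.02. Of 32 genes of epithelial junctions and keratins 5 rose and 7 fell (5 and 10 adjusted over the list alone). DSP and PARD6B (-2.31 ± 0.08), a polarity protein, were among the falls, and CDH1 and KRT19 among the rises, and the list did not pass (adjusted p = 0.379). Of 16 integrins 7 rose and 1 fell (8 and 2 adjusted over the list alone), with ITGA5 higher by 1.16 ± 0.10 and ITGB4 lower (-0.98 ± 0.13). The integrin list gave adjusted p = 0.0273, and adjusted p = 0.25 with an estimated correlation, and its call was lost with quantile normalization. Of 27 matrix proteases and inhibitors 9 rose and 4 fell (10 and 6 adjusted over the list alone), with rises of the plasminogen activator PLAT (4.29 ± 0.08), the metalloprotease ADAM19 (1.96 ± 0.08) and the inhibitor TIMP1 (1.68 ± 0.09). That list gave adjusted p = 0.0323, and adjusted p = 0.25 with an estimated correlation, and with no filter on dim probes the call was lost and the median turned to -0.088. Of 25 collagens 10 rose and 10 fell (the same counts adjusted over the list alone). COL13A1 was higher by 4.75 ± 0.09 and COL4A6 at least 9.26-fold, while COL9A3 fell by 3.80 ± 0.11 and COL11A1 was at least 4.35-fold lower. Of 16 laminin and basement membrane genes 5 rose and 5 fell (5 and 6 adjusted over the list alone), with LAMB3 (3.58 ± 0.17) and LAMB1 (3.05 ± 0.10) among the rises. Neither the collagens (median -0.13, mean 0.33, adjusted p = 0.433) nor the laminins (median -0.15, mean 0.05, adjusted p = 0.95) passed as lists.

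Of the signalling and stress lists given next, those of Notch, hypoxia and immediate early genes passed, while p53 targets and angiogenic factors did not. Of 20 Notch pathway genes 10 fell and 3 rose (11 and 3 adjusted over the list alone), with falls of HES4 (-2.58 ± 0.08) and HEY1 (-1.50 ± 0.09), which Notch activates, and of the ligand JAG2 (-1.28 ± 0.08). The Notch list gave adjusted p = 0.0207, and adjusted p = 0.25 with an estimated correlation, and its call was lost on the in vivo arrays alone. Of 35 hypoxia response genes 15 rose and 6 fell (20 and 7 adjusted over the list alone). The collagen-modifying enzymes LOX (3.26 ± 0.17) and PLOD2 (2.58 ± 0.08) rose, and ADM (adrenomedullin) fell by 1.30 ± 0.07. The hypoxia list gave adjusted p = 0.000452, and adjusted p = 0.25 with an estimated correlation, and its call was lost with only probes above background on all 8 arrays. Of 26 immediate early genes 8 rose and 2 fell (9 and 2 adjusted over the list alone), among them the AP-1 subunits FOSL1 (1.30 ± 0.09) and JUN (0.89 ± 0.10). The list gave adjusted p = 0.0381, and adjusted p = 0.25 with an estimated correlation. Its call was lost in 7 other settings, and the median turned to -0.22 with only probes above background on all 8 arrays. Of 25 p53 targets 8 fell and 1 rose (9 and 1 adjusted over the list alone), including SFN (-1.34 ± 0.08), FDXR (-1.04 ± 0.11) and TP53INP1 (-1.02 ± 0.08), and the list missed the threshold (adjusted p = 0.0579). Panc-1-CTC also had less of the vasoconstrictor peptide EDN1 (-4.06 ± 0.09) and of the guidance protein SEMA3A (-2.02 ± 0.09). These belong to 27 angiogenic factors, of which 12 fell and 5 rose (14 and 6 adjusted over the list alone) without the list passing (adjusted p = 0.0742).

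Of 61 cytosolic ribosomal proteins 18 fell and 1 rose (21 and 1 adjusted over the list alone), with a median of -0.19 that turned to 0.05 with quantile normalization and 0.04 with normexp and quantile normalization. RPS12 fell by 0.75 ± 0.12. The list gave adjusted p = 0.000452, and adjusted p = 0.41 with an estimated correlation. Of 52 oxidative phosphorylation genes 8 rose and 1 fell (6 and 0 adjusted over the list alone), with adjusted p = 0.0349 for the list and adjusted p = 0.509 with an estimated correlation. SDHD rose by 0.54 ± 0.08, a call lost without any 1 of the 4 in vivo arrays and with the mean of its probes, and the list's call was lost without replicate 1 of Panc-1-P in vivo. Of 18 HLA class I and antigen processing genes 5 rose and none fell (the same counts adjusted over the list alone), with adjusted p = 0.0448 for the list and adjusted p = 0.25 with an estimated correlation, and the call was lost when any of 5 single arrays was left out and with the mean of all probes of a gene. Among markers of host cells, which mouse tissue in the tumours could add through probes that bind mouse RNA, 3 of 7 endothelial markers rose and none fell (the same counts adjusted over the list alone). TEK, an angiopoietin receptor, was at least 9.28-fold, ROBO4 at least 1.96-fold and SOX17 at least 1.38-fold higher. The call of SOX17 was lost in 10 settings and that of ROBO4 in 6, most of them with single arrays left out or another scaling. The endothelial list gave adjusted p = 0.0448, and adjusted p = 0.25 with an estimated correlation. Its call was lost in 12 other settings, and its median turned to -0.14 with no filter on dim probes. Of 16 fibroblast and pericyte markers 5 rose and 8 fell (the same counts adjusted over the list alone). PDGFRB was at least 4.48-fold and FAP at least 2.77-fold higher, COL1A2 fell by 1.25 ± 0.08, and the list did not pass (median -0.44, mean 0.06, adjusted p = 0.748).

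**Figure D3:**
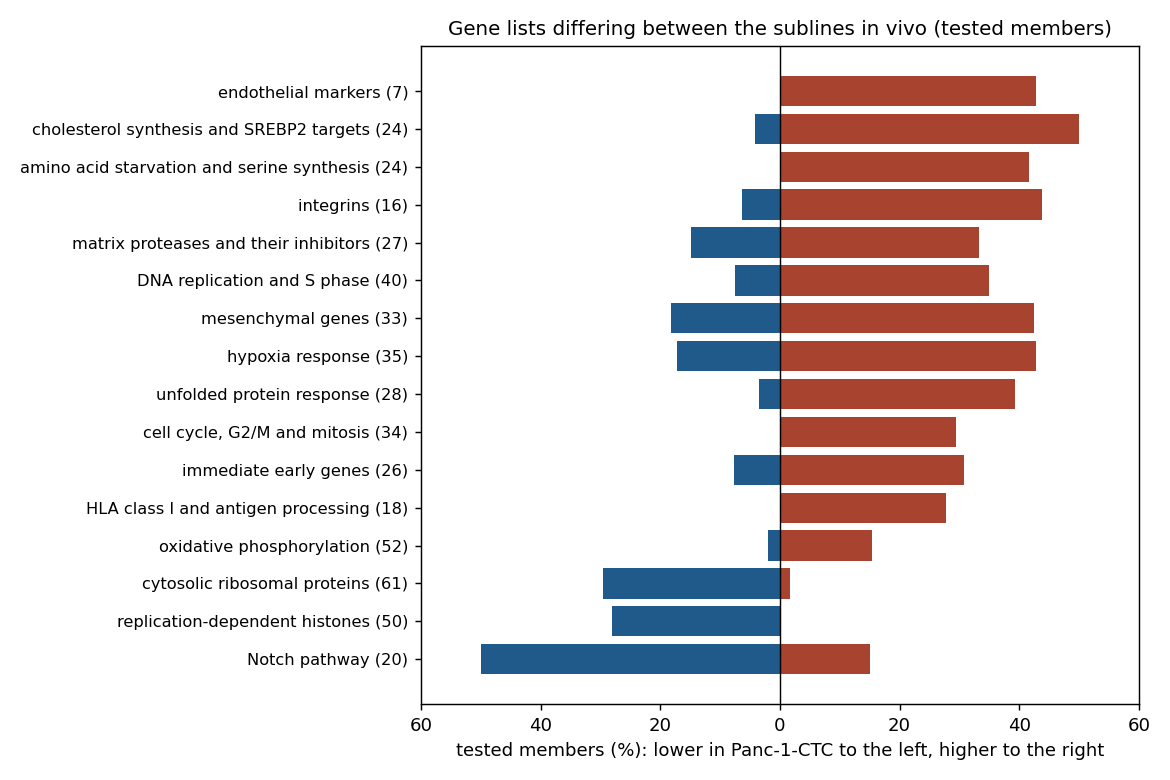
Percent of tested members of each list called higher (right) or lower (left) in Panc-1-CTC than in Panc-1-P in vivo, for the 16 lists past the threshold with the preset correlation, with the number of tested members in brackets. Cholesterol synthesis had 12 of 24 members higher, and no histone of 50 was higher; with quantile normalization the median of the ribosomal proteins turned to 0.05.

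The count of genes in vivo fell to a similar extent whichever in vivo array was left out. It was 1843 without replicate 1 and 2087 without replicate 2 of Panc-1-P in vivo, and 2023 without replicate 1 and 2132 without replicate 2 of Panc-1-CTC in vivo, against 5458 with all arrays. Of the genes named above with no such remark, the calls of RPS12 were lost without either Panc-1-CTC in vivo array, those of XBP1 without replicate 1 and of PLK1 without replicate 2 of either subline in vivo. Another scaling ended the calls of KRT19, INSIG1, CCNE2, RFC2, PDIA6 and COL11A1. The p-values measure only the spread between 2 arrays. The labels do not say whether replicates were separate cultures or animals, and they may be technical. For 724 probes spotted repeatedly, the SD between the Panc-1-P in vivo arrays was 0.066 log2, against 0.053 from the repeat spots. In Panc-1-CTC in vivo it was 0.062 against 0.053, for 731 probes. The in vivo arrays thus differed little beyond spot noise, so each in vivo group may rest on 1 RNA sample. The arrays cannot decide this.

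In vitro the same question was asked of cells in dish culture. The Panc-1-CTC arrays showed more RNA of CBX6, a Polycomb protein, at least 24.7-fold, of TUBB3, a tubulin of neurons and many tumours, at least 20.1-fold, of TGFBI, a secreted matrix protein, at least 17.2-fold, and of IL4R, the interleukin-4 receptor, at least 15.7-fold. Of genes measured in both sublines, VIM was higher in Panc-1-CTC by 3.53 ± 0.08 and the stress transcription factor ATF4 by 4.91 ± 0.08. RAP1GAP, which inactivates the GTPase RAP1 (-8.05 ± 0.14), the RNA-binding protein BICC1 (-7.63 ± 0.18) and the chemokine receptor ACKR5 (-7.37 ± 0.08) were lower. Of 49 oxidative phosphorylation genes above background in at least 1 subline 48 were higher, as were 53 of 60 ribosomal proteins. Over all 12227 features above background in at least 1 subline, 6478 were called higher and 3901 lower. These differences came with 34.5% of probes above background on the Panc-1-CTC arrays against 17.6% on those of Panc-1-P.

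By limma's test 16999 of 21577 features differed in vitro, 6823 higher and 10176 lower in Panc-1-CTC, but 6620 of the calls were on features above background in neither group. Where both groups were above background, 1944 of 5641 features were higher and 3054 lower. The split moved with the scaling, from 40.1% of calls higher to 54.5% with quantile normalization, 57.2% with normexp and quantile normalization, 63.0% with median centring and 28.6% with the 75th percentile taken over the probes above background on all 8 arrays, a setting chosen after seeing the data. The median log2 fold change of all features was -0.58, against 0.13 with quantile normalization and 0.25 with median centring. It also moved with the level of the gene. Among features above background on all 8 arrays it went from -1.39 for the 1329 with a mean log2 signal under 8 in vivo to 2.14 for the 825 with one over 14, while in vivo it went from -0.33 to -0.11. Different probes of 1 gene often parted. Of 2078 genes with at least 2 probes called in vitro, 941 (45.3%) had calls in opposite directions, against 17 of 395 (4.30%) in vivo. Among probes above background in both sublines, a limit set after seeing the data, these were 123 of 290 genes (42.4%) in vitro and 11 of 316 (3.48%) in vivo.

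**Figure D4:**
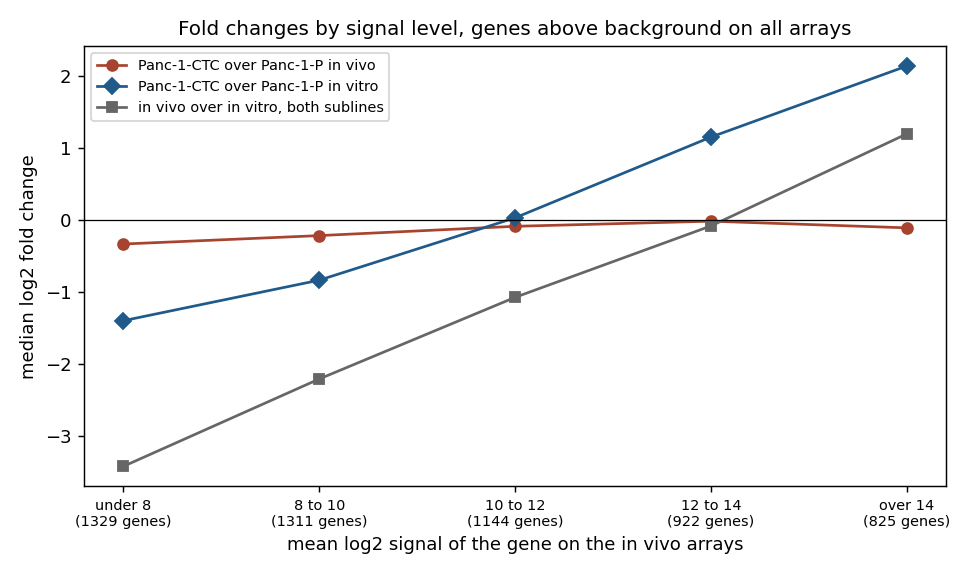
Median log2 fold change by mean log2 signal of the gene on the in vivo arrays, for features well above background on all 8 arrays, in 3 comparisons. In vitro the median went from -1.39 to 2.14 with the level and in vivo over in vitro from -3.41 to 1.20, while the subline comparison in vivo stayed between -0.33 and -0.01.

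The other large rises in vitro were DROSHA, the nuclease that starts microRNA processing (at least 14.6-fold), SMIM29 (at least 16.04-fold), SAE1, part of the SUMO-activating enzyme (at least 10.99-fold), and MFN2, a mitochondrial fusion protein. The 2 probes of MFN2 gave 6.03 and -0.19. The probe at 6.03 had a mean scaled log2 signal of -1.50 in Panc-1-P in vitro, below the percentile used for scaling. On those arrays this percentile lay under the lowest signal called well above background, so the size of the MFN2 rise was not measured. The other large falls were TEF (-7.93 ± 0.43, above background on 1 of the 2 Panc-1-CTC arrays), GPR179 (-7.65 ± 0.35), CCDC66 (-7.22 ± 0.26), BCR and the cancer-testis gene MAGEB6 (at least 53.3-fold). The 3 probes of BCR gave -7.33, 1.34 and -1.05, and the 2 of RAP1GAP gave -8.05 and -1.63. Adjusted p for these 16 genes ranged from 1.31e-06 to 1.91e-05. Of the genes fixed for naming, CD44 was at least 5.30-fold, MET at least 2.38-fold, ZEB1 at least 2.04-fold and KRT19 at least 1.70-fold higher in Panc-1-CTC. The in vitro bounds move with the scaling. With the 75th percentile over probes above background on all 8 arrays, the log2 fold change of CDH2 went from 0.29 to -0.33. Under that scaling, chosen after seeing the data, all in vitro bounds on rises shrink by the same log2 amount. MKI67 passed at 1.92 ± 0.09, with probes at -1.73, 4.47 and 1.92, and ACTB at 1.64 ± 0.07, with a further probe at -0.59. CDH2 (adjusted p = 0.0562) and CDKN2A (0.27 ± 0.14, adjusted p = 0.11) did not pass. CDH1, EPCAM, SNAI2 and CXCR4 were not well above background in either subline, so no fold is given.

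Of 43 lists 9 were higher in Panc-1-CTC in vitro and none lower, and by camera none of the 9 held with an estimated correlation (8 had an unadjusted p under 0.05), each at adjusted p = 0.245 except the S phase list at adjusted p = 0.296. Members were counted when above background in at least 1 subline, which favours rises because the Panc-1-CTC arrays were brighter. Over all 12227 features so chosen 6478 rose and 3901 fell. Of the 5641 features above background in both sublines 1944 rose and 3054 fell. With the first filter, 48 of 49 oxidative phosphorylation genes rose and 1 fell, including COX6A1 (3.93 ± 0.08) and UQCRQ (4.08 ± 0.09). Of 60 ribosomal proteins 53 rose and 4 fell, including RPL23 (4.17 ± 0.08). In the unfolded protein response 22 of 26 rose and 2 fell, including ATF4 and the chaperone HSPA5 (at least 3.98-fold). Of 19 amino acid starvation genes 17 rose and 2 fell, including CBS (3.78 ± 0.07) and PHGDH (at least 2.02-fold). In the G2/M list 27 of 33 rose and 3 fell, including BIRC5 (2.39 ± 0.08) and CEP55 (3.15 ± 0.07), and in the S phase list 27 of 30 rose and 1 fell, including TK1 (2.68 ± 0.08). Of 16 cholesterol genes 14 rose and 1 fell, including DHCR7 (at least 7.52-fold). Of 13 HLA class I genes 10 rose and 2 fell, with HLA-G at 3.35 ± 0.08, and of 16 YAP/TAZ targets 15 rose and 1 fell, with CCN2 at least 3.61-fold and AMOTL2 at least 6.36-fold. Over all tested members, dim ones included, the calls were the same in number adjusted over the list alone. With dim genes held at their bounds the median of the cholesterol list fell from 0.86 to 0, that of the G2/M list from 1.80 to 0.50, of the S phase list from 1.24 to 0.44, of the amino acid starvation list from 2.02 to 0.49 and of the YAP/TAZ list from 1.08 to 0.47. With only probes above background on all 8 arrays, oxidative phosphorylation, ribosomal proteins and the unfolded protein response kept their calls. The G2/M, S phase, amino acid starvation and HLA class I lists lost theirs, and the cholesterol and YAP/TAZ lists had too few members left. Among members above background in both sublines, the medians were 0.21 for G2/M (9 genes) and 0.93 for S phase (9 genes). Those of amino acid starvation (2.21, 6 genes) and HLA class I (1.59, 8 genes) were not under their whole-list medians of 2.02 and 1.38. For these 2 lists the lost call does not show that dim genes carried the rise. The cholesterol call was also lost with normexp and the 75th percentile.

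Over both settings together, 15573 features differed between the sublines, 6512 higher and 9061 lower in Panc-1-CTC, and 4732 of them were above background in all 4 groups. The calls of the single settings overlapped beyond independent lists. In vivo and in vitro shared 1195 features higher in Panc-1-CTC, where independent lists would share 775, and 2027 lower ones, where they would share 1419. Among the 5531 features above background on all 8 arrays, 334 higher calls were shared against 182 for independent lists, and 883 lower ones against 680. Median fold changes in that set were lower for dim features in both settings, from -1.39 to 2.14 in vitro and from -0.33 to -0.11 in vivo. Such a shared trend can raise the overlap and the correlation by itself. The overlap was not tested against lists matched on level. The fold changes of the settings correlated at r = 0.190 across all tested features and r = 0.350 across those 5531, and genes are not independent replicates. MET, KRT19, TGFBI, PHGDH and LAMB3 were higher in Panc-1-CTC in both settings, and RAP1GAP, BICC1 and ACKR5 were lower in both.

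The comparison of tumours with dish culture was limited by the dim in vitro arrays and by the mouse RNA that host cells can add to the tumours. Of host markers, C1QB, a macrophage gene, was at least 5.24-fold and DCN, a fibroblast gene, at least 12.6-fold higher in vivo, and in Panc-1-CTC the haemoglobin gene HBA2 was higher by 5.50 ± 0.29. After scaling, many host markers were called lower in vivo. Of 12 macrophage and leukocyte markers 2 were higher and 10 lower in vivo, of 16 fibroblast and pericyte markers 5 and 9, and of 7 endothelial markers 0 and 6, and none of these lists passed (adjusted p = 0.0794, 0.622 and 0.117). With genes dim in vitro held at their bounds the medians were -1.76 for the first list and 0 for the others, so a fall of the other lists was not measured. The arrays do not tell which rises below are of the cancer cells. The tumours had more RNA of SGK1, a kinase induced by serum and glucocorticoids, at least 50.3-fold, of ZFAND6 at least 27.8-fold, of the prion protein gene PRNP at least 23.3-fold and of MTHFD2, a mitochondrial folate enzyme, at least 21.6-fold. The glycolytic enzyme PGK1 was higher in vivo by 4.76 ± 0.05 and, in Panc-1-CTC, TYMS (thymidylate synthase) by 5.60 ± 0.10. In vitro the arrays showed more of PKD1L2, at least 94.5-fold, of the hormone receptor TRHR, at least 71.1-fold, of GATA2, a transcription factor of blood and endothelium (-6.66 ± 0.06), and of KRT79 (-6.86 ± 0.16). Fold changes here are in vivo over in vitro, averaged over both sublines, from 4 arrays per setting. Where a gene was not above background on the Panc-1-P in vitro arrays alone, the value given is that of Panc-1-CTC, from 2 arrays per setting, and named as such. The in vitro arrays lay in 1 part of the slide and the in vivo arrays in the other, so slide position and setting cannot be told apart.

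In all, 19257 of 21577 features differed between the settings, 8322 higher and 10935 lower in vivo, and among the 5531 above background in all 4 groups 1158 were higher and 4113 lower. The share of calls that were higher, 43.2%, went to 57.5% with quantile normalization, 57.1% with normexp and quantile normalization, 67.0% with median centring and, in the setting chosen after seeing the data, 54.6% with the 75th percentile over probes above background on all 8 arrays. The median log2 fold change of all features was -0.45, and 0.86 with median centring. Panc-1-P differed between the settings in 18906 features and Panc-1-CTC in 17179. The other large rises were CDK2AP1 (5.55 ± 0.08 in Panc-1-CTC), MYL12A (4.84 ± 0.38 in Panc-1-CTC), ARF4 (at least 35.03-fold), CCDC90B (at least 24.7-fold) and GALNT7 (at least 20.05-fold). The other large falls were ZNF497 (-8.27 ± 0.06, with its other probe at -1.82), P2RY10 (at least 48.5-fold), CEACAM19 (-6.63 ± 0.09) and MIEF1, whose probe with the highest signal gave -7.29 while its other 2 probes rose, the lower of them at 1.96. Adjusted p for these genes over both sublines ranged from 9.37e-08 to 6.87e-06. Of the genes fixed for naming, CD44 (2.62 ± 0.10), MET (2.27 ± 0.08) and ZEB1 (1.38 ± 0.34) were higher and KRT19 (-2.37 ± 0.19) was lower in vivo in Panc-1-CTC, and MKI67 (-2.04 ± 0.07) was lower over both sublines. ZEB1 had a second probe, at 0.72 over both sublines. The probes of MKI67 parted, with 0.55 and -0.07 for the others. ACTB was lower by this scaling (-1.39 ± 0.05) and higher with quantile normalization (0.51), with normexp and quantile normalization (0.49) and with normexp and the 75th percentile (0.16).

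Lists of growth and metabolism were mostly higher in the tumours. Of 43 lists 16 were higher and 1 lower in vivo, and by camera none held with an estimated correlation, at adjusted p from 0.179 to 0.616 (11 had an unadjusted p under 0.05). Set against random lists matched on the signal in the tumours, 9 of the 17 list medians lay inside the central range, 7 above and 1, the histones, below it. Inside lay the ribosomal proteins (percentile 45.2), the G2/M list (80.2), the S phase list (88.1) and HLA class I (84.8), so their rise was not beyond that of other genes as bright, though all but the ribosomal proteins lay above the matched median. Single genes marked with Panc-1-CTC carry the value of that subline. Of 52 oxidative phosphorylation genes 48 rose and 4 fell, with NDUFB3 at 3.90 ± 0.07 in Panc-1-CTC, and of 61 ribosomal proteins 53 rose and 7 fell, with RPL15 at 4.78 ± 0.06 (adjusted p = 0.181 and adjusted p = 0.294 with an estimated correlation). Of 24 cholesterol genes 21 rose and 3 fell, and of 18 HLA class I genes 17 rose and 1 fell, including the peptide transporter TAP1 (3.32 ± 0.08 in Panc-1-CTC), both at adjusted p = 0.179 with an estimated correlation. Of 24 amino acid starvation genes 20 rose and 4 fell, including MTHFD2 and CEBPG (3.10 ± 0.08 in Panc-1-CTC). Of 40 S phase genes 32 rose and 5 fell, including TYMS, with a fall of CLSPN (claspin) by 4.28 ± 0.07. In the G2/M list 27 of 34 rose and 7 fell, including CCNB1 (2.62 ± 0.08 in Panc-1-CTC), and of 35 hypoxia genes 25 rose and 8 fell, including PGK1 and DDIT4 (5.30 ± 0.11 in Panc-1-CTC). These 4 lists gave adjusted p = 0.181 with an estimated correlation, and all 4 lost their call when only probes above background on all 8 arrays were tested, with the G2/M and hypoxia medians turning to -0.36 and -0.88. The G2/M call was also lost with quantile normalization. Of 25 NF-kB, cytokine and chemokine genes 16 rose and 7 fell, including NFKBIA (4.45 ± 0.09 in Panc-1-CTC) and the chemokine CCL2 (3.39 ± 0.09 in Panc-1-CTC), at adjusted p = 0.358 with an estimated correlation. The call was lost in 3 other settings, and with no filter on dim probes the median turned to -1.85. With genes dim in vitro held at their bounds the median was 0 instead of 0.94. Of 36 interferon-stimulated genes 24 rose and 8 fell, including IFITM2 (0.72 ± 0.10 in Panc-1-CTC), at adjusted p = 0.391 with an estimated correlation, and the median of 0.84 was 0 with dim genes at their bounds and turned to -0.19, with the call lost, with normexp and the 75th percentile. Of 19 stem cell and circulating tumour cell markers 14 rose and 5 fell, including PLS3 (2.35 ± 0.12 in Panc-1-CTC), at adjusted p = 0.181 with an estimated correlation, and the call was lost under each of the 5 other scalings. The median of 1.58 was 0.04 with dim genes at their bounds, and with no filter on dim probes the median turned to -0.39. Of 50 replication-dependent histones 37 fell and 9 rose, including H2BC21 (-4.41 ± 0.06), at adjusted p = 0.616 with an estimated correlation, with a median of -0.75 that turned to 0.55 with median centring and 0.45 with normexp and the 75th percentile. The histone call was also lost with no filter on dim probes, with only probes above background on all 8 arrays and with the 75th percentile over those probes. The counts of members given here were the same adjusted over the list alone.

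Whether the subline difference depended on the setting was tested by the interaction term of the same fit. By limma's test 13802 features passed, 7556 with a more positive difference in vivo and 6246 with a more negative one, and 4123 of them were above background in all 4 groups. PRSS3 (trypsinogen) was measured on all arrays and turned round, at -3.60 in vitro and 3.51 in vivo, an interaction of 7.11 ± 0.11. TMEM121 turned the other way, higher in Panc-1-CTC in vitro, where Panc-1-P was not above background, and at -2.21 in vivo. APCDD1L and SELENBP1 were above background only in Panc-1-CTC tumours. CBX6, SMIM29, IL4R and TUBB3 differed in vitro by at least 24.7-fold, 16.04-fold, 15.7-fold and 20.1-fold, and in vivo had log2 fold changes of 0.13, -0.43, -0.01 and -0.38. TEF and RIMS3 were lower in Panc-1-CTC in vitro, where RIMS3 was not above background in that subline, and in vivo had -0.64 and 0.54. Adjusted p for these 10 interactions ranged from 9.11e-06 to 0.000182. The dimness of the Panc-1-P in vitro arrays enters each of these terms.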

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

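Of the tests in this part, those of spike-in signal, of parallel loss of signal, of opposite probe calls, of host cell markers and those limited to measured probes were chosen after the results they bear on were seen.

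The subline difference depended on the setting, by limma's interaction term, for 13802 features. The fitted interactions named were 7.71 for APCDD1L, 7.29 for TEF, 7.11 for PRSS3, 6.99 for RIMS3 and 6.97 for SELENBP1, and -6.94 for TMEM121, -6.52 for CBX6, -6.34 for SMIM29, -6.15 for IL4R and -6.09 for TUBB3. All of these but PRSS3 rest on at least 1 group with an array not well above background, so their size is not measured. In control probes that no comparison uses, of 109 not known to be spiked in, 6 were well above background on both arrays of Panc-1-P in vitro, 7 in Panc-1-CTC in vitro, 6 in Panc-1-P in vivo and 3 in Panc-1-CTC in vivo. The probe ERCC-00113_271 had a mean log2 signal of 10.46 in Panc-1-P in vitro and from 4.85 to 6.33 in the other groups, and ETG09_35454 had 7.23 in Panc-1-CTC in vitro and from 2.37 to 2.58 in the others.

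The first pattern weighed was the low signal of messenger RNA on the in vitro arrays, where the mean 75th percentile was 3.90 lower on the log2 scale than in vivo. A failed hybridisation or scan was argued against by the spike-in probes, which fell by only 0.43. Less of the same RNA was argued against in Panc-1-P by 96 of 6093 probes that were 4 times or more brighter in vitro than in vivo. That lay above a bound of 1 in 100 written after the data were seen. In Panc-1-CTC only 19 were, under that bound, so this count leaves less RNA open there. The ribosomal RNA probes, which less of the same RNA would lower too, averaged 16.98 in Panc-1-CTC in vitro and 16.88 in vivo. That argues against less RNA as the whole cause in Panc-1-CTC. Degraded or unevenly labelled RNA may account for the pattern. Opposite calls of probes of 1 gene were made for 45.3% of genes in vitro and 4.30% in vivo. Among probes above background in both sublines these were 42.4% and 3.48%. This cannot single out degraded RNA, because median fold changes in vitro also moved with signal level, from -1.39 to 2.14. Such a trend can part a bright and a dim probe of 1 gene. The files also give no probe positions to test it by. Growth in a dish instead of a tumour could not be decided from the correlation of the settings' difference between the sublines, 0.836 across 5531 genes, because every array of a setting shares its brightness. It stays open as an untested biological difference, as does a mix of both.

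The second pattern was the rise of 9 gene lists in Panc-1-CTC in vitro, where a loss of signal that depends on a gene's level may be enough for most of them. Compared with random lists matched on the signal in the tumours, the list medians lay at percentile 84.32 for ribosomal proteins, 85.08 for S phase, 44.13 for cholesterol synthesis, 97.43 for the unfolded protein response, 95.43 for amino acid starvation, 44.41 for HLA class I and 84.01 for YAP/TAZ targets, all inside the central 95% of the random lists. Oxidative phosphorylation lay above it at 99.11, and at 99.67 for its 26 members measured in both sublines, so it passed the bound set beforehand. That list had been called on the same fold changes, and the random lists were drawn gene by gene. Its place is therefore no independent evidence against that loss. The G2/M list lay at 98.45 but at 58.71 for its 9 measured members, so the bound was met only through genes near the floor. That loss stays open for both lists, as do degraded RNA and a difference between the sublines. In the same comparison in vivo, 12 of the 16 called lists lay above and 3 below the matched range. Those lists had been called on the same fold changes, and the random lists were drawn gene by gene. Their place outside the range is therefore no independent support.

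The third pattern was the set of 5458 features that differed between the sublines in vivo. A uniform change in the share of mouse host cells was argued against as a single cause by the host cell lists. Of their 60 tested members 17 were higher and 13 lower in Panc-1-CTC, 7 of the 60 also standing in other lists. Host markers passed more often than features at large, of which 25.3% did, so a host contribution stays open. A change that differs between host cell types could move markers both ways, which this test cannot exclude. Abundant host genes parted as well, with COL1A1 at 1.04 ± 0.09, DCN at -1.29 ± 0.18, COL1A2 at -1.25 ± 0.08, the haemoglobin gene HBA2 at -0.28 ± 0.29 and the macrophage gene C1QB at -0.32 ± 0.15, so a change in the make-up of the host cells stays open. Differences in copy number between the sublines may account for part of the set. Ranked in vivo fold changes of genes 10 to 20 places apart on a chromosome correlated at 0.111 across genes, against at most 0.00988 in 1000 random orders. In vitro this correlation was 0.0173, with no random orders drawn. A copy number difference would be present there too, but the dim in vitro arrays limit that comparison. Window medians of 25 genes correlated at 0.237 between the in vivo and in vitro comparisons, against at most 0.139 in random orders. Those orders also broke the pairing of genes between the settings, whose fold changes already correlated at r = 0.190 across all tested features. The window correlation therefore does not bear on copy number. Whether most of the calls have this origin was not tested, and regulation that differs between the sublines stays open.

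Other splits of the arrays were counted for the comparisons with 4 arrays a side, with the other factor as a term. For the sublines, 1 of 34 splits, the real one with 3431 features, gave as many, and the highest of the others gave 460. For the settings the count was also 1 of 34, with 15922 features against 0 in the others. These counts cannot exclude chance, since 1 of 34 is the smallest share that could be reached. In the other splits at least part of the real difference also goes into the residual spread, which lowers their counts. The labels do not state whether the arrays are independent. The split that parts the arrays like the other factor could not be fitted.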

How the results depend on the processing

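Of the settings in this part, the 75th percentile over probes above background on all 8 arrays, the counts by background in the compared groups and the list test on the in vivo arrays alone were chosen after seeing the data. Brightness over background limits the in vitro arrays, with 17.6% and 34.5% of probes above it.

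Outside the in vivo comparison, counts rose and fell with the number of features tested, which these settings change by construction. In vitro 29575 features passed with no filter, 5190 with only probes above background on all 8 arrays, 10379 among those above background in at least 1 compared group and 4998 in every compared group. In the same settings (no filter, all 8 arrays, every compared group) the counts were 26600, 5035 and 4732 over both settings, 33781, 5452 and 5516 for the settings in Panc-1-P, 31566, 5350 and 9925 in Panc-1-CTC, 34162, 5474 and 5271 over both sublines, and 21383, 4563 and 4123 for the interaction. In vivo 4376 passed with no filter, which kept 3619 of the 5458 calls, and 2752 with only probes above background on all 8 arrays, where 1824 of the 5458 calls could be tested and 1811 were kept, so these counts did not follow the number tested and the cause was not tested. The main fit shares 1 spread over all 8 arrays. Replicates differed more in vitro (SD 0.189 log2 in each subline) than in vivo (0.130 in Panc-1-P, 0.139 in Panc-1-CTC). With only the arrays compared, which leaves the in vitro spread out, 11123 passed in vivo, and 11619 did with array weights. How far the spread explains this was not tested. The count in vivo was 2776 with quantile normalization, 2445 with normexp and quantile normalization and 12226 with normexp and the 75th percentile, and the cause was not tested. It was 1843 to 7217 when 1 array was left out, lowest without Panc-1-P in vivo replicate 1 (1843), then without Panc-1-CTC in vivo replicate 1 (2023), Panc-1-P in vivo replicate 2 (2087) and Panc-1-CTC in vivo replicate 2 (2132). Leaving out 1 leaves a lone array that is assumed to vary like the others. Of the 5458 in vivo calls, 2720 were kept in direction with quantile normalization and 5355 with only the arrays compared. Lists passing went from 9 to 17 with no filter and 4 with probes above background on all 8 arrays in vitro, from 16 to 10 with those probes in vivo, and from 17 to 4 between the settings, and for the lists the cause was not tested. With an estimated correlation 0 passed in each of the 3 comparisons, though with an unadjusted p under 0.05 camera gave 8, 7 and 11. On the in vivo arrays alone 13 lists passed.

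Values that turned sign are given next, with the cause not tested except where probes changed. With quantile normalization they were SNAI2 (0.24) and CDKN2A (-0.13) in vitro, SNAI2 (1.46) and ACTB (0.51) between the settings, and in vivo the ribosomal protein (0.053) and collagen (0.012) medians and between the settings the fibroblast and pericyte median (0.16). With median centring they were ZEB1 (0.002) and MKI67 (0.084) in vivo, SNAI2 (0.13), CDKN2A (0.14) and the histone median (0.55) between the settings, and the collagen median (0.006) in vivo. With normexp and quantile normalization they were CXCR4 (0.057) and CDKN2A (-0.12) in vitro, SNAI2 (0.57) and ACTB (0.49) between the settings, and the ribosomal protein median (0.037) in vivo and the fibroblast and pericyte median (0.034) between the settings. With normexp and the 75th percentile, all between the settings, they were CDH1 (-0.01), EPCAM (-0.60), CXCR4 (-0.70), ACTB (0.16), histones (0.45) and interferon-stimulated genes (-0.19). With the 75th percentile over probes above background on all 8 arrays CDH2 (-0.33) and CDKN2A (-0.34) turned in vitro. Where the probes changed, MFN2 in vitro gave -0.19 on its other probe, MKI67 in vivo 0.18 and CDH2 between the settings -0.036 as the mean of their probes. Only probes above background on all 8 arrays gave medians of -0.023 for mesenchymal and -0.22 for immediate early genes in vivo, and -0.36 for G2/M and -0.88 for hypoxia between the settings. No filter gave -0.088 for proteases and -0.14 for endothelial markers in vivo, and -1.85 for NF-kB and -0.39 for stem cell markers between the settings.

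Of the called genes followed through the settings in vivo, some of which the text does not name, 63 of 85 kept their call and direction in every setting in which they were tested, as did 44 of 49 in vitro, 60 of 67 between the settings and all 10 interactions. Only 22, 22, 17 and 1 of these called genes, in that order, had a probe above background on all 8 arrays and went through that setting. Of the called lists, the estimated correlation aside and where tested, 6 of 16 did so in vivo, 4 of 9 in vitro and 4 of 12 followed between the settings.

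The labels give the replicates only a number, and their deviations correlated between groups at -0.01 to 0.12 over all tested features and at -0.04 to 0.28 over measured probes, so pairing is not excluded. A replicate block gave 16888 features in vitro, 4589 in vivo, 15382 over both settings, 18801 in Panc-1-P and 17010 in Panc-1-CTC between the settings, 19186 over both sublines and 13572 for the interaction, and 9, 15 and 17 lists. It ended the in vivo calls of the HLA class I list and of VIM.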

Other observations

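The windows and their flanking genes were chosen after their values were seen, while the test of gene order was planned before.

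Genes that lie next to each other shifted together in vivo in a few stretches of the genome. Of 519 windows of 25 neighbouring tested autosomal genes, 7 had a median log2 fold change beyond 0.564, the most extreme of 1000 random orders, 2 higher and 5 lower in Panc-1-CTC. Of the 5 lower ones, 3 followed each other, from CHMP7 to ELP3 (median -0.72, 13 of 25 genes lower), from ZNF395 to ERLIN2 (-0.69, 14 lower) and from PLPBP to NKX6-3 (-0.68, 9 lower), and their in vitro medians were -0.90, -0.85 and -1.57. The window from HSF1 to COMMD5 had -0.62 in vivo with 14 genes lower and none higher, and 0.10 in vitro, and that from LILRB3 to COX6B2 had -0.60 in vivo and -0.45 in vitro. The higher ones ran from CLCN2 to LPP (0.70 in vivo, -0.66 in vitro, 12 genes higher in vivo) and from ZNF767P to SMARCD3 (0.58 in vivo, 0.04 in vitro). These stretches are hypothesised to differ in copy number between the sublines, which is consistent with the correlation of 0.111 at 10 to 20 places and which a measurement of DNA could test. The arrays measured RNA only, and 2 of the 7 windows had the opposite sign in vitro. The correlation at 10 to 20 places was only 0.0173 in vitro.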
